A study of Mus musculus with 6 samples.

How the data were processed

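Decidual, placental and embryonic tissue of the mouse was profiled together on 6 single-channel Affymetrix arrays, 3 from wild-type mice and 3 from mice with a null mutation of Prl8a2, the gene of decidual prolactin-related protein (dPRP). Per the labels, all tissue was taken on day 7.5 of pregnancy, the strain background was C57BL/6, total RNA was extracted with Trizol, and biotin-labelled cRNA was prepared by the manufacturer's protocol. The deposited table held 1 log2 value per probe set and array, made by the authors with RMA (robust multi-array average) per the submitters' processing notes. RMA corrects background, quantile-normalizes the arrays and summarises the probes of a set on the log2 scale, so its values are comparable between arrays for 1 probe set but not between probe sets. The software that ran RMA, its version and a genome build are not given in the sources used here. The values ran from 2.66 to 14.94, and array medians lay between 5.34 and 5.38. RMA values carry no background flag, so a low value is only a low signal and a fold change from it is compressed. The number of arrays limits the precision.

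Of 45101 probe sets, 64 Affymetrix control sets were left out and 45037 were tested. The platform annotation gave a single gene symbol for 34945 of them, several for 932 and none for 9160, and only those with a single symbol were named. Of these, 34741 matched a gene of the mouse RefSeq table (assembly GRCm38.p6) by Entrez identifier, and no symbol changed in the update. Because no build is named for the array annotation, this table served only for chromosomes and gene order. A gene was represented by its probe set with the highest mean over the 6 arrays, which gave 18193 genes.

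Groups were taken from the sample titles. The main test was limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes on the deposited values, genotype as the only term, a two-sided moderated test and Benjamini-Hochberg adjustment over all probe sets tested. A call needed an adjusted p under 0.05. Standard errors (SE) of log2 changes come from this fit, except those said to be across genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Gene lists were fixed before the data were examined: 23 lists covering stress responses, the prolactin family, the cell types that such tissue could hold, cell cycle and metabolism. The 22 lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over those lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera also uses fewer degrees of freedom, so a higher p there need not reflect genes that vary together. Calls near Prl8a2, within 100 measured genes on either side, were compared with all other genes by Fisher's exact test, two-sided.

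The genes named were fixed by rule: Prl8a2, then the 12 largest rises and 12 largest falls among genes with an adjusted p under 0.05 and no overlap between groups, then up to 4 members of smallest p from each list, and Hspa5, Ddit3, Vegfa, Prl3c1, Gzma and Pecam1 in any case. Genes named outside this rule are said to have been chosen after their values were seen. The test was tried on simulated data of 45037 probe sets for this comparison, with 200 changed in each of 10 simulations. It recovered 52.8% of changes of 0.5 on the log2 scale, 97.6% of changes of 1 and 100% of changes of 2, and 5.33% of the calls were false. A list shifted by 0.2 was found in 100% of simulations, and 7 of 210 tests of other lists were called. The simulated probe sets varied independently of each other. The share of other lists called therefore does not hold for lists whose genes vary together, such as cell cycle, with an estimated correlation of 0.312.

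The alternatives fixed before the data were examined changed the normalization, the filter on dim probe sets, the variance model, array weights, a replicate block, the threshold or minimum change, the list test, the probe set of a gene and the window around Prl8a2, and left out each array in turn. The alternatives that left out genes of chromosomes 8 and 13, or Prl8a2, were added after the data were seen. The labels call the samples biological replicates but do not say how many conceptuses each array held or whether each came from another female, so the p-values measure the spread between these samples.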

Results

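The data were 6 expression arrays of mouse decidual, placental and embryonic tissue from gestation day 7.5, 3 of wild-type and 3 of dPRP-null mice. dPRP is a hormone-like protein of the prolactin family made by decidual cells, the uterine stromal cells that surround the implanted conceptus. Pairs of arrays correlated at 0.995 to 0.998 within groups and at 0.994 to 0.997 between groups across probe sets (Pearson), so the ranges overlap. The first principal component held 39.7% of the variance and placed the 3 dPRP-null arrays at 14.3 to 17.3 and the 3 wild-type arrays at −30.4 to −5.13. The third wild-type array lay farthest out, at −30.4.

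The question was which transcripts differ when dPRP is missing. Prl8a2 itself (1 probe set, chromosome 13) had a mean of 14.91 ± 0.02 (SD, n = 3) on the log2 scale in wild-type tissue. It was 7.65 ± 0.94 (SD, n = 3) in dPRP-null tissue, with single arrays at 8.72, 7.26 and 6.97. The difference was −7.26 with SE 0.36, or 153-fold lower in dPRP-null, with a limma adjusted p of 4.68e-05; this fold is a lower bound if the wild-type signal was saturated, which RMA values do not show. Every array thus went with its label, although which part of the gene the probe set covers relative to the null mutation is not given in the sources used here.

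Beyond Prl8a2, 9 of 41 genes for protein folding and degradation in the endoplasmic reticulum (ER) and 4 of 41 genes of the PERK-ATF4 stress response rose in dPRP-null tissue. As groups they passed camera with the preset correlation but had an adjusted p of 0.0996 and an adjusted p of 0.0715 with an estimated correlation. Derl3, a component of ER-associated degradation, was 6.29-fold higher, Herpud1 3-fold and Creld2 2.76-fold, and Hspa5, the main ER chaperone BiP, was 1.67-fold higher. The largest single rise was Pdgfrl, on chromosome 8, at 11.5-fold. The largest falls among genes called, after Prl8a2, were Mid1, at 3.91-fold, and Tmem267, at 3.54-fold. With limma, 145 of 45037 probe sets had an adjusted p under 0.05, 96 higher and 49 lower in dPRP-null. Taking each gene by the probe set that represents it, 62 genes were called, 41 higher and 21 lower. Genes called only on another probe set are not among them. Of the probe sets called, 32 changed at least 2-fold, 24 up and 8 down. All 145 had 3 arrays of one group beyond the 3 of the other, as did 19.9% of all probe sets, where chance gives 10%. Leaving out the first wild-type array left 53 calls, the second 93, and the dPRP-null arrays in turn 65, 46 and 56.

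The list of ER chaperones and ER-associated degradation had 41 measured genes. Of these, 9 were higher, 0 lower and 32 not past the threshold over all genes, and 21 were higher and 1 lower when adjusted over the list alone. Such genes had been reported on from these samples before the list was written, so the list is not independent evidence of its direction. The 9 were Derl3, Herpud1, Creld2, Pdia4, Sdf2l1, Sel1l, Hspa5, Hsp90b1 and Manf. Derl3 rose from 7.61 ± 0.35 to 10.27 ± 0.05 (SD, n = 3 each), by 2.65 with SE 0.15 and a limma adjusted p of 7.19e-05. Herpud1, which brings misfolded proteins to degradation at the ER membrane, rose by 1.59 with SE 0.07 and an adjusted p of 2.78e-05, and both of its probe sets were called. Creld2, an ER protein induced by stress, rose by 1.46 with SE 0.08 and Sdf2l1 by 0.83 with SE 0.07. Hspa5 rose from 13.32 ± 0.02 to 14.07 ± 0.04 (SD, n = 3 each), with an adjusted p of 0.00185; of its 2 other probe sets, 1 was called at 1.05 and the other differed by 0.19. The mean change of the list was 0.35, 37 of 41 members were positive, and camera gave an adjusted p of 3.88e-17, which was an adjusted p of 0.0996 with an estimated correlation. Among members not past the threshold over all genes, Pdia6 differed by 0.32 and Dnajc3 by 0.28, while Calr differed by 0.03 and Spcs3 by 0.01. These and the other members listed were chosen after their values were seen.

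**Figure D1:**
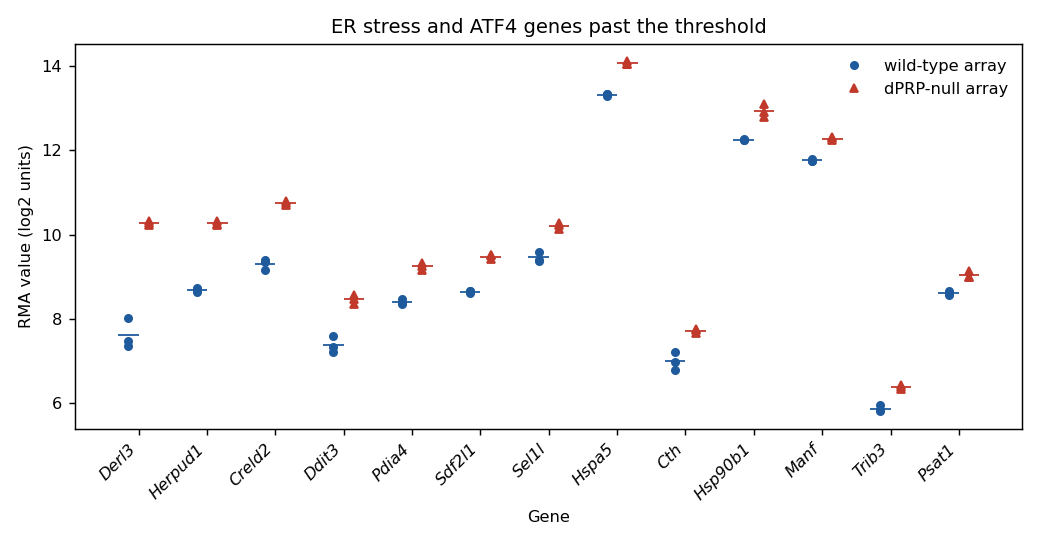
Values of the 13 ER and ATF4 list genes past the threshold, with 1 point per array on the log2 RMA scale (circles wild-type, triangles dPRP-null, 3 arrays each) and short lines at group means. Every dPRP-null array lies above every wild-type array for each gene, for example 10.22 to 10.31 against 7.36 to 8.01 for Derl3.

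The list of the PERK-ATF4 branch, which adjusts amino acid supply and translation under stress, had 41 measured genes, 4 higher, 0 lower and 37 not past the threshold. Adjusted over the list alone, 9 were higher and 0 lower; this list too is not independent evidence, for the same reason. Ddit3, the stress transcription factor CHOP, rose 2.13-fold, from 7.37 ± 0.19 to 8.46 ± 0.10 (SD, n = 3 each, limma adjusted p of 0.00242), while its second probe set differed by 0.18. Cth, an enzyme of cysteine synthesis, rose by 0.73, Trib3, a target of CHOP, by 0.53 and Psat1, an enzyme of serine synthesis, by 0.44. The mean change was 0.16 and camera gave an adjusted p of 1.19e-07, which was an adjusted p of 0.0715 with an estimated correlation. The Psat1 call was lost in each of the 6 fits that left out 1 array, and those of Cth and Trib3 in 4 each.

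Genes of squamous epithelial differentiation were lower on average. None of the 48 measured passed over all genes with limma, but 1 was higher and 9 lower when adjusted over the list alone. The genes of this list had also been reported on from these samples, so it is not independent evidence. Perp, a desmosome protein, differed by −0.70, Ppl by −0.43, Sprr2h, a cornified envelope protein, by −1.21 and Sbsn by −0.34, with adjusted p between 0.0822 and 0.1 over all genes. The mean was −0.23 and camera gave an adjusted p of 3.53e-06, which was an adjusted p of 0.0996 with an estimated correlation. The third wild-type array was 2.07-fold above the mean of the other 2 for Sprr2h, and the list mean without that array was −0.18. It was −0.43 over probe sets above the median mean level and −0.58 at a mean level of at least 6.

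Of 18 measured prolactin family genes, 2 were lower, 0 higher and 16 not past the threshold, and 1 was higher and 4 lower when adjusted over the list alone. Prl3c1, which lies 3 measured genes from Prl8a2, fell from 13.31 ± 0.16 to 12.76 ± 0.00 (SD, n = 3 each), by 0.56 with a limma adjusted p of 0.0435, and the call was lost in 5 of the 6 fits without 1 array. Prl8a9, Prl7c1 and Prl4a1, the last chosen after its value was seen, differed by 0.57, −0.34 and −1.25. The list mean was −0.75 and −0.37 without Prl8a2, where camera gave an adjusted p of 0.0112. With all members camera gave an adjusted p of 0.000876, which was an adjusted p of 0.277 with an estimated correlation. Prolactin family genes were also higher in the third wild-type array, by 0.73 on average against the other 2 without Prl8a2. Without that array and Prl8a2 the list mean was −0.13 and Prl4a1 differed by −0.68. With all members the list mean was −1.20 over probe sets above the median mean level and at a mean level of at least 6.

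Cell cycle genes were slightly higher, with 43 of 48 members positive and a mean of 0.15, but 0 passed by limma over all genes or over the list alone. Nusap1 differed by 0.32, Ttk by 0.40, Cdc20 by 0.26 and Prim1 by 0.29, each with its 3 dPRP-null arrays above the wild-type ones. Camera gave an adjusted p of 1.17e-09, which was an adjusted p of 0.326 with an estimated correlation. In the third wild-type array these genes lay 0.06 below the other 2 on average.

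Trophoblast genes, markers of the fetal part of the placenta, had a mean of −0.18 over 52 members with 0 past the threshold by limma over all genes or over the list alone (Cts8 −0.57, Psg21 −0.32, Krt8 −0.53, Mmp9 −0.31). Camera gave an adjusted p of 0.00163, or an adjusted p of 0.365 with an estimated correlation. The list was 0.29 higher on average in the third wild-type array than in the other 2, and its mean without that array was −0.08. It was −0.27 with either filter on dim probe sets. Cholesterol and steroid genes had a mean of −0.15 over 31 members, 0 past over all genes and 2 lower over the list alone (Lss −0.33, Dhcr7 −0.56, Scarb1 −0.37, Sc5d −0.28), with a camera adjusted p of 0.00802 and an adjusted p of 0.655 with an estimated correlation. Yolk sac endoderm genes had a mean of −0.09 over 46 members, 0 past over all genes and 1 lower over the list alone (Fgg −0.43, Ihh −0.25, Col4a2 −0.23, Nostrin 0.24), with a camera adjusted p of 0.0376 and an adjusted p of 0.326 with an estimated correlation. Without the third wild-type array, the adjusted p became 0.482 for the cholesterol list and 0.682 for the endoderm list, and these lists were 0.30 and 0.20 higher in that array than in the other 2. The endoderm list also passed no more without the first or the third dPRP-null array, at adjusted p of 0.0659 and 0.0714, with array weights (0.0779), over probe sets above the median mean level (0.142), at a mean level of at least 6 (0.171) or with chromosomes 8 and 13 left out (0.0689).

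Among uterine natural killer cell genes, Gzma, a granzyme of killer cells encoded on chromosome 13, was the member of 35 past the threshold. It rose from 9.93 ± 0.03 to 10.62 ± 0.20 (SD, n = 3 each), by 0.69 with a limma adjusted p of 0.0271, and the call was lost in 5 of the 6 fits without 1 array. The other members went the other way on average, with a list mean of −0.08, and over the list alone 1 was higher and 2 lower (Klra8 −0.42, Itga2 −0.35; Klrd1 differed by −0.45). Camera gave an adjusted p of 0.0407, an adjusted p of 0.655 with an estimated correlation and an adjusted p of 0.739 without the third wild-type array, where these genes were 0.20 above the other 2 on average. It was 0.071 and 0.167 without the first and the second dPRP-null array, 0.159 with array weights and 0.133 without cross-hybridising probe sets; the list mean was −0.14 without the second wild-type array.

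Decidual stroma genes had 1 higher, 2 lower and 43 not past the threshold of 46, with 2 higher and 7 lower over the list alone. The 1 that rose was Ndp, the secreted ligand norrin, by 0.59 with a limma adjusted p of 0.0398, a call lost in 5 of the 6 fits without 1 array and after quantile normalizing again (0.0574), and the 2 that fell were Prl8a2 and Prl3c1; Aoc1 differed by −0.32. The list mean was −0.24, with a camera adjusted p of 0.0876 and an adjusted p of 0.314 with an estimated correlation, and −0.09 without Prl8a2 (0.201) or with chromosomes 8 and 13 left out (0.371). With Prl8a2 kept in it, the list passed camera without the third wild-type array (0.0239) and after quantile normalizing again (0.0317). It also passed above the median mean level (0.0046), at a mean level of at least 6 (0.00312) and with an intensity trend (0.0353). These settings were not run without Prl8a2. Endothelial and angiogenic genes had 0 of 49 past the threshold with limma and a camera adjusted p of 0.912, with a median of 0.00 just above zero and a mean of −0.04, while over the list alone 1 was higher and 4 were lower. The 4 were Lipg, Notch4, Fabp4 and Cdh5, at −1.29, −0.43, −0.65 and −0.30. Pecam1 and Vegfa differed by −0.18 and −0.03, with limma adjusted p of 0.551 and 0.927. The hypoxia list had 0 of 42 past the threshold over all genes or over the list alone and a camera adjusted p of 0.565 (Adm −0.52, Lox −0.30, P4ha2 0.29, Egln1 −0.27).

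The remaining lists did not pass either, and no member passed over all genes with limma on the probe set that stood for it. For Igf1, however, its 3 other probe sets were called, higher in dPRP-null. Camera adjusted p was 0.0736 for embryonic germ layers (54 genes; Prdm1 −0.38, Hesx1 −0.30), 0.0876 for myeloid cells (43 genes; Csf1r −0.23, Cd74 −0.24) and 0.117 for erythroid cells (22 genes; Alas2 −0.57, Fech −0.20). It was 0.162 for interferon response (46 genes; Rsad2 −0.34, Ifit1 −0.30), 0.328 for T and B cells (26 genes; Cd3d 0.24, Cd247 −0.25) and 0.7 for extracellular matrix (51 genes; Vcan 0.43, Adamts1 −0.29) and for progesterone and oestrogen response (35 genes; Igf1 0.42, Errfi1 −0.23). It was 0.905 for uterine epithelium (41 genes; Cdh1 0.33, Wnt7a −0.27) and for cytosolic heat shock and immediate early genes (37 genes; Ccn1 −0.34, Hspa1b 0.40), and 0.984 for smooth muscle (32 genes; Pdgfrb 0.25, Synm 0.27). Mean and median differed in sign for uterine epithelium (0.0174 and −0.00771), smooth muscle (−0.0134 and 0.00725) and extracellular matrix (−0.0269 and 0.00978). Some of these lists passed when 1 array was left out: erythroid cells without the first wild-type array (adjusted p of 0.029) or the third dPRP-null array (0.0381), and myeloid cells (0.0157) and interferon response (0.00524) without the second wild-type array. With all arrays, myeloid cells and interferon response passed after quantile normalizing again (0.0346 and 0.0317), above the median mean level (0.0197 and 0.0309) and at a mean level of at least 6 (0.00941 and 0.0185), and embryonic germ layers with the mean of each gene's probe sets (0.0216). With an estimated correlation the adjusted p was 0.655 for erythroid and for myeloid cells, 0.868 for interferon response and 0.277 for embryonic germ layers. The third wild-type array was above the other 2 by 0.51 on average for erythroid, 0.16 for interferon and 0.10 for myeloid genes, and without it the list means were −0.0369, 0.0103 (the sign turned) and −0.0209. Over the list alone, the embryonic list had 1 gene lower, the heat shock list 1 higher and 2 lower, the matrix list 2 higher and 3 lower, and the steroid response list 1 higher. The list of Y-linked genes and Xist had 4 measured members and was not tested; Xist was 11.77 in wild-type and 11.70 in dPRP-null tissue, and Kdm5d 3.70 and 3.59.

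**Figure D2:**
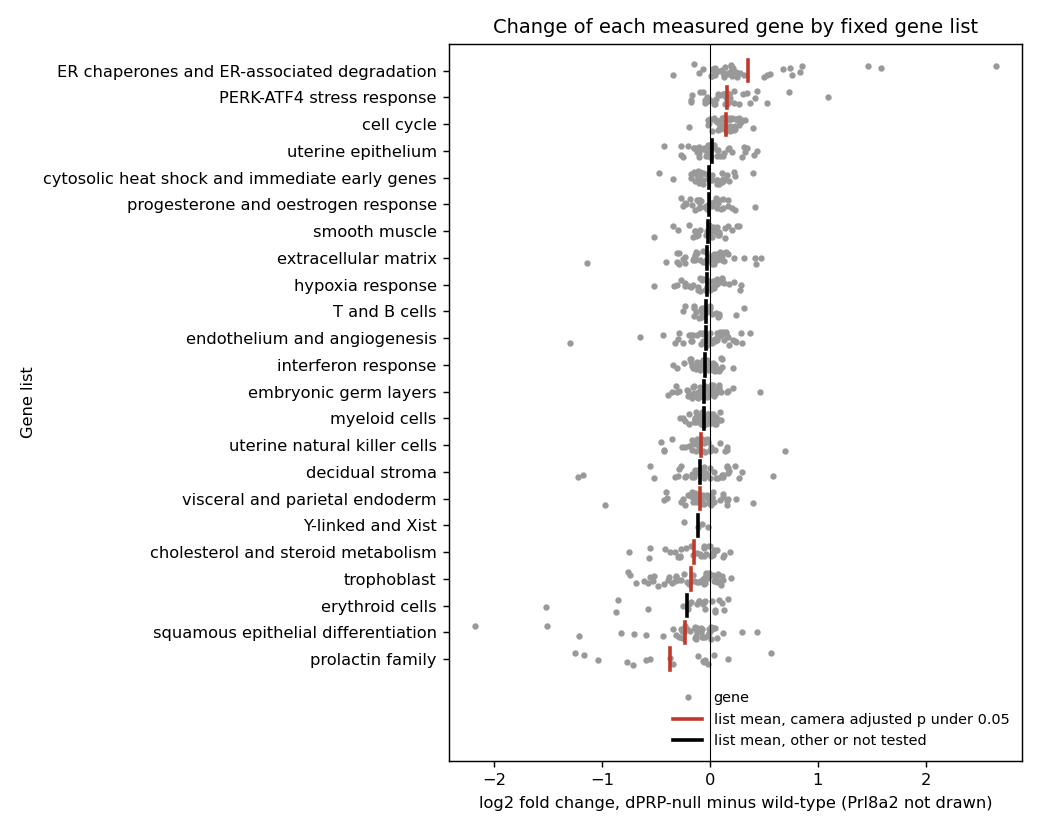
Each grey point is the log2 fold change of 1 gene, dPRP-null minus wild-type, by gene list, and bars are list means, red where camera's adjusted p was under 0.05 with the preset correlation. Prl8a2 is not drawn and not in the drawn means. The ER list lies farthest to the right, with a mean of 0.35.

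In all, 9 of 22 lists passed with the preset correlation, 0 with an estimated correlation and 3 with fry (ER, PERK-ATF4 and squamous). Other ways of splitting the 6 arrays into 3 and 3 gave up to 9 lists, so the number of lists does not exceed that of other splits. The planned split test did not cover single lists. For cell cycle another split gave a lower unadjusted camera p (1.28e-11 against 1.06e-10). The same held for the trophoblast, prolactin, natural killer cell, cholesterol and endoderm lists. For the ER, PERK-ATF4 and squamous lists the real split gave the lowest camera p. It did so too for embryonic germ layers, which did not pass (unadjusted camera p of 0.0335 against 0.0387). With 10 splits in all, the lowest place gives no support to a single list.

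Among the other genes with the largest rises, Nnt, a mitochondrial enzyme that makes NADPH, rose by 1.68 with SE 0.10 and a limma adjusted p of 9.83e-05, and 1 of its 2 other probe sets was also called. Pdgfrl rose from 4.10 ± 0.13 to 7.62 ± 0.31 (SD, n = 3 each), by 3.52 with SE 0.14. Cdc14b, a phosphatase, rose by 1.63, Efcab7 by 1.54, Hfe, a regulator of iron uptake, by 1.25, Rec114 by 0.96 and Frg1 by 0.85. Ctse, the protease cathepsin E, rose by 1.16 on a probe set with a cross-hybridising suffix, while its other probe set differed by −0.11. Among the falls, Mid1, a ubiquitin ligase, fell by 1.97 on 1 probe set while its 2 others differed by 0.06 and 0.05 at low signal. Tmem267 fell by 1.82, Porcn, which acylates Wnt proteins, 2.83-fold, Gm13306 by 1.21, Arhgef6 by 0.97, Crct1 by 0.87, Cyfip2 by 0.86, Pdxk by 0.85, Dpep1 by 0.82, Ly6k by 0.82, Malat1, a long noncoding RNA, by 0.74 and Purg by 0.67. Of the 6 other probe sets of Malat1, 1 was called, at −0.52, and the others lay between −0.45 and −0.01; its call was lost with the mean of its probe sets (−0.32, adjusted p of 0.0566) and without cross-hybridising ones (−0.23, 0.361). Other probe sets not called differed by 0.33 for Hfe, −0.06 for Cyfip2, −0.08 for Ly6k, −0.21 and −0.49 for Pdxk and −0.36 for Purg, and with the mean of a gene's probe sets the calls of Cyfip2 (−0.54, adjusted p of 0.0895) and Purg (−0.52, 0.0749) were lost. Of the 32 named genes called, 14 were called in every fit without 1 array, among them Derl3, Herpud1, Creld2, Ddit3, Hspa5, Sdf2l1, Pdgfrl, Nnt, Mid1 and Tmem267.

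The surroundings of Prl8a2 held more called genes than the rest of the genome in gene order. Among the 200 measured genes closest to it, 100 on each side, 4 were called (Hfe, Prl3c1, Serpinb6c and Elovl2), or 2% against 0.314% of 17829 other genes. Serpinb6c and Elovl2, which makes long-chain fatty acids, rose by 0.51 and 0.72; they were named after their values were seen. The odds ratio was 6.48 with a 95% confidence interval of 1.69 to 17.8 (Fisher's exact test, p = 0.00441). By chromosome, 21 tests in all, chromosome 13 had 10 of 701 genes called besides Prl8a2 (adjusted p = 0.00202 by Fisher's exact test) and chromosome 8 had 9 of 932 (adjusted p = 0.0367). The 10 included Gzma, Nnt and Tmem267, and the 9 included Pdgfrl, Frg1 and Herpud1. The neighbourhood result rests on few genes, and its odds ratio lay between 0 and 4.97 when arrays were left out in turn, with p of 0.178 or more in every such fit: 0 without the first wild-type array or the third dPRP-null array, 2.08 without the second wild-type array, 2.68 without the third wild-type array, and 4.07 and 4.97 without the first and second dPRP-null arrays.

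**Figure D3:**
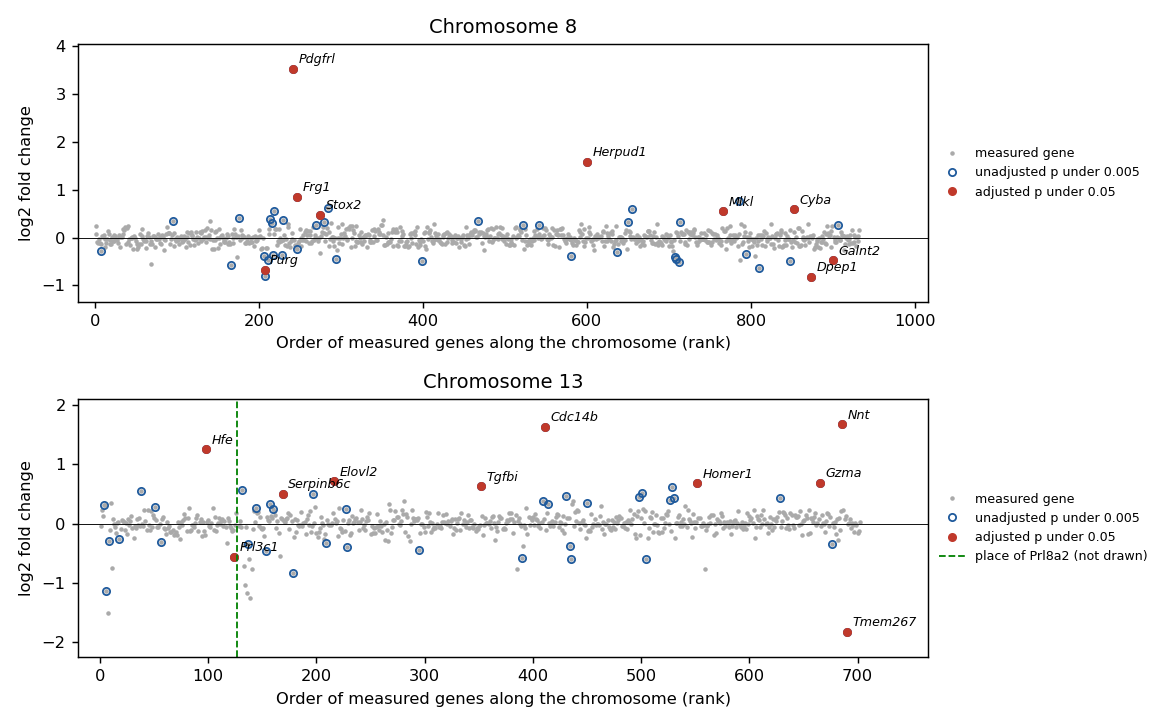
Log2 fold change, dPRP-null minus wild-type, of each measured gene against its rank in gene order on chromosomes 8 and 13. Blue circles have an unadjusted limma p under 0.005 and red points an adjusted p under 0.05; the dashed line marks Prl8a2, which is not drawn. Nnt at 1.68 and Tmem267 at −1.82 lie 4 measured genes apart near the end of chromosome 13.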

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

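The alternatives that left out genes of chromosomes 8 and 13, or Prl8a2, were chosen after seeing the data; the others were planned. The fall of Prl8a2 kept its direction and its call in every setting run. The count of probe sets called (all, higher and lower) was 275, 158 and 117 over probe sets above the median mean level, 338, 187 and 151 at a mean level of at least 6, 524, 265 and 259 with an intensity trend in the prior variance, 339, 184 and 155 at an adjusted p under 0.10, and 37, 28 and 9 with treat at 1.2-fold. The filters tested fewer probe sets, and the last settings changed the threshold itself. Leaving out 1 array gave 46 to 151 calls, 35 to 84 higher and 11 to 67 lower, the most without the third wild-type array. The neighbourhood odds ratio was 9.69 (p = 0.00451) with 50 genes on either side, 3.91 (p = 0.0232) with 200, 2.62 (p = 0.049) above the median mean level, 3.18 (p = 0.00318) with the intensity trend, 3.02 (p = 0.0294) at an adjusted p under 0.10, 2.35 (p = 0.0506) at a mean level of at least 6, 4.49 (p = 0.079) with at least 1.5-fold, 0 with treat at 1.2-fold, and 0 to 4.97 without 1 array; the p-values are from Fisher's exact test, and the cause was not tested. With an estimated correlation 0 lists passed, and the adjusted p was 0.277 for the prolactin family (mean −0.754), 0.0996 for the ER list (0.35), 0.0715 for the PERK-ATF4 list (0.163) and 0.0996 for the squamous list (−0.227). With fry 3 lists passed, and the prolactin list (−0.754) had an adjusted p of 0.0998. Ctse turned to −0.1088 without cross-hybridising probe sets, since another probe set then stood for it. Of 32 named genes called, 32 were called with array weights, 31 after quantile normalizing again and 13 with treat. RMA values have no measured background, which limits folds of dim genes such as Pdgfrl.

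The replicate numbers are shared between groups, but same-numbered arrays did not deviate together (r = 0.0499, −0.0143 and 0.0906 across probe sets), and not every array correlated best with its own number. A replicate block gave 136 calls, 85 higher and 51 lower, 9 lists, a Prl8a2 change of −7.26, and a neighbourhood odds ratio of 3.52 (p = 0.117, Fisher's exact test). Of the 32 named genes called, 27 kept their call with it, and Porcn, Prl3c1, Trib3, Psat1 and Ndp lost it, at adjusted p of 0.0522 to 0.0903 with the changes unaltered.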

Other observations

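The tests of other splits of the arrays were planned before their results were seen; the other tests reported here, and the genes they name, were chosen after the results had been seen.

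The third wild-type array differed from the other 2 in genes of yolk sac, blood and placenta, among others. Hbb-bh1, an embryonic haemoglobin, was 9.10 there and 4.43 and 4.77 in the other 2, or 22.6-fold higher. Afp, made by yolk sac endoderm, was 10.2-fold higher, the embryonic haemoglobin Hba-x 6.41-fold, Rhox6 6.53-fold and the trophoblast gene Tpbpa 4.7-fold. The prolactin family gene Prl7a1, also of trophoblast, was 4.86-fold higher, Klk7, a kallikrein, 6.68-fold, Ada, adenosine deaminase, 8.25-fold and Rimklb 13.9-fold. Lists outside these tissues rose too. Over members with a mean level above 6, natural killer cell genes were 0.271 higher (SE across genes 0.05), interferon 0.17 (0.0196) and cholesterol 0.263 (0.0716). Trophoblast genes were 0.472 higher (0.124), erythroid 0.166 (0.125) and endoderm 0.145 (0.0921). In all, 66 genes were over 2-fold higher in that array and 0 were over 2-fold lower. Without it, 151 probe sets and 71 genes were called; 46 genes were called in both fits, 25 only without it and 16 only with all arrays. Genes called only without it included Klk7, which fell by 1.26, and Lipg, an endothelial lipase, Sprr2h, Calm4, Htra3 and Adamts5, a matrix protease, which fell by 0.87, 0.86, 0.85, 0.78 and 0.70. Of these 25 genes, 8 rose, most of all Sprr2f, by 0.69, opposite to its family member Sprr2h.

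A probe set of Smarcb1, a chromatin remodelling gene and the measured gene next to Derl3, rose by 1.94 with a limma adjusted p of 0.000103, while its 2 other probe sets differed by −0.18 and 0.10. Hsp90b1 and the adjacent 1810014B01Rik rose by 0.68 and 0.80, and Maob and the adjacent Ndp by 0.56 and 0.59, while Acsbg1 and Crabp1, 3 measured genes apart, went opposite ways, by −0.57 and 0.72.

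The rise of ER and ATF4 genes in dPRP-null tissue, for which a response to the loss of dPRP remains a hypothesis, was weighed against other explanations. DNA of another strain on chromosome 13 or in the chromosome 8 window described next was weighed as acting on its own genes. It does not account for the members, since 0 of the 13 called lay there. Herpud1 lies on chromosome 8 outside that window. Such DNA elsewhere stays open, as Hsp90b1 forms a close pair of calls on chromosome 10. On that chromosome Derl3 lies next to Smarcb1, of which 1 probe set was called at 1.94. An effect of such DNA on distant genes stays open as well. The third wild-type array was not needed, since the mean of the ER list was 0.376 without it. More plasma cells, which secrete antibody and are rich in such genes, stay open: Ighm, Jchain, Cd79a, Cd79b and Pou2af1 changed by 0.0572 on average with SE 0.0426, but all except Ighm (6.57 and 6.58) lay near the floor, and Jchain, which marks secreting cells, differed by 0.32 with SE 0.13. The real split of the arrays gave 145 probe sets and the highest of the other splits 0, so 1 of the 10 splits gave as many, and for lists 3 of the 10 splits gave as many as the real 9, the highest other split giving 9; 10 splits are too few for a share under 0.05.

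Called genes lay close together more often than shuffled ones. There were 6 pairs within 10 measured genes where 10000 shuffles gave 1.94 on average (permutation p = 0.017), and a window of 30 genes on chromosome 8, from Tti2 to Tusc3, held 10 genes at an unadjusted p under 0.005 where 0.887 were expected and the highest of 1000 shuffles was 8. Among the 6 pairs were Pdgfrl and Frg1, 5 measured genes apart on chromosome 8, which rose by 3.52 and 0.85. They lie just past that window, at ranks 242 and 247 in gene order against 230 for Tusc3. Mismatches to the probes in dPRP-null arrays alone would lower signals, but 2 of the 10 called genes on chromosome 13, Prl8a2 left out, were lower and 8 higher; in the window 6 of the 10 genes were lower and 4 higher, so there mismatches stay open. DNA of another mouse strain or substrain around Prl8a2 and elsewhere may have remained in the dPRP-null mice; Nnt, which is disrupted in C57BL/6J but not in many other strains, lies on chromosome 13, and no genotype was analysed here. A response shared by neighbouring genes stays open too, since close pairs remained more frequent with chromosomes 8 and 13 left out (permutation p = 0.02, 4 pairs against 0.98). Acsbg1 and Crabp1 among these 4 pairs, and Nnt and Tmem267 on chromosome 13, went opposite ways, which goes against such a response for those pairs. The others of the 4 went the same way. Hsp90b1 with 1810014B01Rik and Maob with Ndp rose, while Mid1 and G530011O06Rik on chromosome X differed by −1.97 and −0.46.

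For the third wild-type array, RNA degradation was tested with actin control probe sets, whose 3′ minus 5′ difference was 0.4648 there and 0.4765 to 0.6089 in the other arrays, which argues against it. More conceptus tissue stays open: trophoblast genes with a mean level above 6 were 0.472 higher, but embryonic germ layer genes 0.049 higher (SE across genes 0.0665). That SE takes genes as independent and does not measure the spread between arrays. More advanced gestation in that array, with dPRP-null tissue on the other side, predicted a negative correlation across genes between the 2 differences from the other wild-type arrays, and r was 0.151, positive but below the lowest of 0.42 in 100 simulations of the shared arrays, so it could not be decided; the covariance was 0.00492 against a simulated 0.0061. Of the 66 genes higher in that array, 55 (83.3%) were lower in dPRP-null than in the other 2 wild-type arrays, against 51.8% of all genes, a share that was seen before this explanation was weighed and does not test it.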
